A study of Mus musculus with 16 samples.

How the data were processed

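Tissue was captured by laser from frozen sections stained with cresyl violet, per the labels' protocols. Dorsal and ventral cloaca came from 4 embryos at E10.5, and hindgut and urethra from 4 other embryos at E13.5. RNA was amplified from sub-nanogram inputs with a whole-transcriptome kit before Illumina library construction, per the labels' protocols. How the pieces were outlined is not given in the sources used here. Per the labels, every embryo was a wild-type CD1 male, and the sample names tie both regions to the same numbered embryo.

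The values deposited by the authors are FPKM (fragments per kilobase of transcript, scaled to the mapped fragments) in 2 deposited tables, with 1 column per region, per the file headers. Cufflinks 2.2.1 and the build mm10 are named in the submitters' processing notes. The aligner, the annotation, the use of strand and the way the 4 libraries of a region were combined are not given in the sources used here. Without strand, reads of overlapping or antisense genes cannot be told apart. The age of each table rests on the table's name and its regions on the column headers. No other sample columns were present. The low values, multiplied by exon length, were checked for steps of whole reads. At most 23.3% of values lay within 0.1 of a whole number of any common step, where 20% would by chance, so that the depth stays unknown.

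Each table had 23234 features with the same names and spans, of which 23083 matched a RefSeq symbol or synonym of GRCm38.p6, the assembly that mm10 represents. A locus start in the tables equals the RefSeq start minus 1 for 11197 of 22813 features compared, so 1 was added to print positions counted from 1. There were 271 features with joint gene names and 3801 whose locus span is shared with another feature. Values of features that share a span are uncertain. Among the genes named in the text these are Adamtsl5, Dlx6, Cldn3, Evx1, Msx1, Bmp4, Shh, Lgr5, Hoxa5, Hoxd3, Tagln, Cnn1, Calml4, Lrmp, Lrrtm1, Dll4, Lcp1 and Nefm. Values of 0 can be failed estimates, so genes are said to be listed at 0 and no fold is given against them. A ratio on the log2 scale that rests on such a value depends on the pseudocount.

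The planned test was a linear model on log2 values per library with the embryo as a block, with set tests on that fit. It needs values per library and was not possible here. As laid down beforehand for tables of means, it was replaced by a description of the deposited values without a test. Per age, genes with an FPKM of at least 1 in either region were kept, and the difference of log2(FPKM + 1) was taken as ventral minus dorsal. A pseudocount of 1 understates the change of low genes. A minimum in either region also lets in genes through the region in which they are higher. A gene was counted at a difference of at least 1 on this scale, a size rule and not a significance threshold. No level was compared across ages by a test.

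Gene lists were fixed before the data were examined. There were 29 lists with 619 entries and 581 distinct genes, of which 4 matched no feature. For each list the median difference of the kept members was set among 10000 random lists of the same size, matched on 20 bins of mean expression. The percentile describes these libraries and is not a p-value. The mean had the other sign than the median for these lists: at E10.5 endoderm and epithelium (-0.11), hedgehog (-0.02), retinoic acid (0.21), smooth muscle (-0.29), neurons (-0.22) and germ cells (0.06), and at E13.5 hedgehog (-0.06), FGF (-0.04), nephric duct (0.24) and mesothelium (0.26). On data simulated from the real levels at E10.5, 100% and 98.0% of genes planted 3 log2 units and 1.5 log2 units lower ventrally were counted, and 0% of unchanged genes. Those planted 1.5 log2 units higher in urethra at E13.5 were counted at 98.0%, and all other planted sizes and directions at 100%. The step ran on 8436 and 8576 genes at the 2 ages, all with a mean of at least 5 FPKM. Its noise was a fixed setting. That noise was narrower than the SD of 0.41 over proteasome, complex I and translation initiation genes at E10.5. The 0% follows from that setting and does not measure false calls in the data. Of 100 random lists, 7.0% fell outside the central 95% at either age.

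Named genes followed a rule also fixed before. It took 10 genes per age and direction with the largest difference and at least 5 FPKM in the higher region, up to 4 members per list past the threshold, and 15 genes in any case. The parts of the rule that need a test or each embryo could not be applied. Some genes that the rule takes are not reported here. Short non-coding RNA features held 3 and 7 of the 10 places for ventral and dorsal cloaca, and 7 and 7 for urethra and hindgut. Their FPKM depends on a very short length, so the text takes the next 10 genes without them, a choice made after the values were seen. Mir3096 is named in the closing section only. Chga, Upk1a, Grhl3, Krt17, Klf5 and Pparg, and in the closing section Krt15, Sfn, Upk2, Cyba, Ctsc, Arhgdib, Lcp1, Tff3, Tspan8, Isx, Cdh17, Slc26a3, Car1, Muc13 and Cdhr5, were also named after their values were seen.

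Alternatives were pseudocounts of 0.1 and 5, no minimum, a minimum of 5 FPKM, upper-quartile scaling and quantile normalization. Leaving out short RNA features, features that share a span, and features listed at 0 in a region was added after the data were seen. Calculations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.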

Results

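RNA was sequenced from tissue cut by laser from stained frozen sections of male wild-type CD1 mouse embryos, an outbred stock. At E10.5 the cloaca, the chamber that the gut and the urinary tract share in the early embryo, was captured as a dorsal and a ventral part. At E13.5 its later derivatives, the hindgut on the dorsal side and the urethra on the ventral side, were captured. Each age had 4 embryos and each embryo gave both regions, so that 16 libraries fall into 4 groups of 4. The deposited tables give 1 FPKM value per gene for each region and age, and no value per library. The depth of the libraries is unknown. No spread between embryos, standard error or p-value could be given for any gene, and no difference below has a replicate check. Levels at the 2 ages come from tables that were normalized separately. A ratio below is the difference of log2(FPKM + 1), and a gene was counted as higher in a region when that difference was at least 1, which is 2-fold on that scale.

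The study set out to build an atlas of gene expression in the developing genital tubercle and urethra, and the first comparison asks which genes set the future urethral side of the cloaca apart from the future hindgut side at E10.5. The ventral cloaca held far more RNA of Crabp1, a retinoic acid binding protein, at 278 FPKM against 2.85 in the dorsal cloaca. Dlx5, a homeobox transcription factor gene of limb and genital development, stood at 110.0 against 0.86 FPKM, and Inhba, which encodes a subunit of activin, at 53.2 against 0.056. The dorsal cloaca held more RNA of Sst, the somatostatin gene, at 32.0 against 0.056 FPKM, and of Cdx2, a master regulator of intestinal identity, at 15.5 against 0.15. Of the 12379 genes with an FPKM of at least 1 in either region, 1308 were at least 2-fold higher ventrally and 1191 dorsally, and 9880 were within 2-fold. With a pseudocount of 5 in place of 1 the counts were 401 and 325, and with a minimum of 5 FPKM 823 and 691.

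The other leading ventral genes were Gfra2 at 57.1 against 0.072 FPKM, Dusp5 at 67.1 against 0.34, Mgp at 193 against 2.82, Hdc at 32.4 against 0.016 and Gm16065 at 32.2 against 0.057. Dlx6, the neighbour of Dlx5, stood at 34.8 against 0.024 FPKM, and Adamtsl5 at 34.5 FPKM and listed at 0 dorsally. The loci of both are shared with other features in the tables, so their reads are less certain to be their own. Other leading dorsal genes were Clca3 at 198 against 8.05 FPKM, Fuom at 22.4 against 0.30, Scnn1a at 21.4 against 0.68, Fbxo27 at 12.7 against 0.053 and Vstm2b at 20.0 against 0.67. Apoa1 at 22.6 FPKM and 1700013G23Rik at 12.7 FPKM led on the dorsal side as well and were listed at 0 ventrally. On mm10, Crabp1 (XLOC_021106) spans 54764808 to 54773109 of chromosome 9, Dlx5 (XLOC_017008) 6877805 to 6882068 of chromosome 6, and Cdx2 (XLOC_016345) 147300900 to 147307249 of chromosome 5.

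Genes of urethral and urothelial identity stood higher on the ventral side at E10.5. Of 22 list members above the minimum, 14 were higher ventrally and 3 dorsally, with a median ratio of 1.2 at percentile 100 of 10000 random lists of matched expression. Trp63, the master gene of stratified epithelium, stood at 86.7 FPKM against 5.94, Krt5 at 17.7 against 0.26, Perp at 73.1 against 7.15 and Gata3 at 38.9 against 7.08. Krt14 stood at 7.76 FPKM and was listed at 0 dorsally. Upk1b, a uroplakin of the bladder lining, had 7.17 FPKM against 0.029, while Upk3a stood at only 0.10 FPKM ventrally and was listed at 0 dorsally. The 3 members higher dorsally were Upk1a, the uroplakin with the highest level, at 94.3 FPKM against 28.8, Grhl3 at 7.08 against 1.52, and Krt17 at 1.21 and listed at 0 ventrally. Genes of surface ectoderm and epidermis, a list that shares 9 genes with the former, had 11 of 13 members higher ventrally. The 2 members higher dorsally were again Grhl3 and Krt17, and the median was 2.47 at percentile 100. Trp63, Krt5, Krt14 and Perp are in both lists, so their values cannot tell urethral identity from surface ectoderm.

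Hindgut and intestine genes leaned to the dorsal side at E10.5, with 5 of 13 members higher dorsally, 3 ventrally and a median of -0.86 at percentile 0.20. The median was -0.38 with no minimum, -0.37 with a pseudocount of 5, -0.26 with a minimum of 5 FPKM and -0.04 over all 30 members, 9 of which were listed at 0 in both regions. Besides Cdx2, Onecut2 stood at 4.79 FPKM dorsally against 0.43 and Hnf4a, a regulator of gut and liver epithelium, at 2.02 FPKM and listed at 0 ventrally. Evx1, a homeobox gene of the posterior embryo, went furthest of the 3 members higher ventrally, at 31.2 FPKM against 5.10. General genes of endoderm and epithelium showed no lean, with 19 of 24 members within 2-fold, 4 higher dorsally, 1 ventrally and a median of 0.01 at percentile 53.7 that fell on the other side of 0 under both other scalings, at -0.01 and -0.06. Shh, a hedgehog ligand gene of cloacal epithelium, stood at 684 FPKM ventrally and 623 dorsally. Foxa1 stood at 57.2 FPKM ventrally and 124 dorsally, Foxa3 at 0.45 and 5.39, Cldn3 at 7.28 and 25, Rab25 at 6.10 and 16.0, and Foxa2 at 25.5 and 17.7. Of 22 members of the intestinal secretory list only 6 passed the minimum at E10.5, and 5 of these were higher ventrally, with a median of 1.15 at percentile 99.9. The median was 0.18 with no minimum, 0.46 with a pseudocount of 5 and 0 over all 22 members, of which 11 were listed at 0 in both regions. The 5 were Sct, the secretin gene, at 76.9 against 3.89 FPKM, the homeobox gene Isl1 at 137 against 65.3, Tph1 at 2.56 against 0.17, Chgb at 1.62 against 0.11 and Chga at 1.12 against 0.044.

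Genes of the Wnt and BMP pathways were higher ventrally as groups at E10.5. For Wnt, 14 of 25 members were higher ventrally and 2 dorsally, with a median of 1.09 at percentile 100 that was 0.52 with a pseudocount of 5 and 0.55 with no minimum. The ligand Wnt6 stood at 25.5 FPKM against 0.33, its signalling enhancer Rspo2 at 17.4 against 0.040, the transcription factor Lef1 at 73.1 against 5.64 and the antagonist Dkk1 at 7.19 against 0.22. Wnt5a had 29.3 FPKM against 11.2. For BMP and TGF-beta, 11 of 20 members were higher ventrally and 2 dorsally, with a median of 1.09 at percentile 100 that was 0.54 with a pseudocount of 5 and 0.39 with no minimum. Bmp4 stood at 72.1 FPKM against 15.8 and its target Msx2 at 87.9 against 10.2, while Msx1 stood at 3.95 FPKM and was listed at 0 dorsally. For FGF, 5 of 20 members were higher ventrally and 1 dorsally, with a median of 0.37 at percentile 93.7. Fgf8 stood at 8.42 FPKM ventrally and was listed at 0 dorsally, Fgf18 at 8.48 against 0.64, Spry2 at 9.55 against 1.55, and the receptor gene Fgfr4 went the other way at 5.82 against 23.5. Hedgehog genes showed no lean, with 2 of 16 members higher ventrally, 4 dorsally and a median of 0.14 at percentile 71.3. Gli3 stood at 24.1 FPKM ventrally against 10.8, while Foxf1 at 1.28 against 7.08, Foxf2 at 3.34 against 9.66 and Gas1 at 8.66 against 20.3 were lower ventrally.

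In the Notch list 5 of 14 members were higher ventrally and 2 dorsally at E10.5 (median 0.14, percentile 62.2), among them Hey2 at 5.71 against 0.98 FPKM, Jag1 at 5.94 against 1.32 and Notch1 at 5.91 against 1.44, with Mfng at 0.36 against 3.09. In the Eph and ephrin list 4 of 16 were higher ventrally and 2 dorsally (median 0.04, percentile 52.6; -0.01 under quantile normalization). Efnb2, a membrane-bound ephrin, stood at 124 FPKM against 22.6, Efnb1 at 9.55 against 2.27 and Efna3 at 8.23 against 1.94, and Efnb3 at 4.02 against 13.9. In the retinoic acid list 5 of 17 were higher ventrally and 3 dorsally (median -0.31, percentile 2.85): the synthesis enzyme gene Aldh1a2 stood at 6.01 FPKM ventrally against 27.8 and the degradation enzyme gene Cyp26b1 at 1.21 against 8.35, while the receptor gene Rarg stood at 8.69 against 1.77. Posterior Hox genes had 4 of 14 members higher ventrally and none dorsally, although their median was 0.02 at percentile 49.9 and lay at -0.01 and -0.04 under the other scalings. The 4 were Hoxa13 at 188 against 53.3 FPKM, Hoxd13 at 199.6 against 98.4, Hoxd12 at 38.9 against 7.65 and Hoxc11 at 8.25 against 0.79; for Hoxd13 upper-quartile scaling gave a ratio of 0.98, just below 2-fold. Anterior and middle Hox genes had 3 of 21 members higher ventrally and 3 dorsally (median -0.30, percentile 3.51), with Hoxd1 at 46.9 against 21.2 FPKM, Hoxa7 at 8.08 against 3.13, Hoxc6 at 0.20 against 3.42 and Hoxa5 at 5.28 against 15.4.

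The second comparison asks the same of the urethra and the hindgut at E13.5. The hindgut held an intestinal set of transcripts: Lgals4 and Lgals6, near-identical galectin genes read here as 1 feature, stood at 268 FPKM against 0.81 in the urethra, Hnf4a at 34.5 against 0.16 and Hoxb13 at 227 against 4.04. The urethra held 46.9 FPKM of Dlx5 against 0.13 in the hindgut, 146 of Krt14, a keratin of basal cells, against 4.04, and 131 of Apoe, an apolipoprotein gene, against 3.52. Of 12369 genes above the minimum, 515 were at least 2-fold higher in urethra and 568 in hindgut, and 11286 were within 2-fold. With a pseudocount of 5 the counts were 173 and 227, with one of 0.1 they were 864 and 822. With a minimum of 5 FPKM they were 298 and 387.

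The further leading hindgut genes were 2610528A11Rik at 60.4 against 0.38 FPKM, Fxyd4 at 123 against 3.61, Calml4 at 41.2 against 0.71, Lrmp at 23.4 against 0.27, Clca4 at 28.9 against 0.60, Akr1c19 at 20.5 against 0.20 and Tmem45b at 21.8 against 0.30. Further leading urethral genes were Hdc, the histidine decarboxylase gene, at 28.0 against 0.12 FPKM, Gm16065 at 25.6 against 0.12, Msx2 at 19.4 against 0.077, Lrrtm1 at 18.8 against 0.050, the netrin receptor gene Unc5c at 33.4 against 1.1 and Gata3 at 29.5 against 1.08. On mm10 the joint feature of Lgals4 and Lgals6 (XLOC_017889) spans 28833794 to 28841703 of chromosome 7, Hoxb13 (XLOC_002950) 96194361 to 96196599 of chromosome 11, and Krt14 (XLOC_003854) 100203162 to 100207510 of the same chromosome.

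Of 20 hindgut and intestine genes above the minimum at E13.5, 15 were higher in hindgut and 1 in urethra, with a median of -2.32 at percentile 0 that was -1.11 with a pseudocount of 5 and -1.53 with no minimum. Gpa33, an intestinal surface antigen gene, stood at 23.2 FPKM in hindgut against 0.42, and Cdx1 at 18.3 against 0.37. Cdx2 was listed at 0 in the hindgut and at 0.025 FPKM in the urethra. Lgr5, a gene of gut stem cells, had 3.87 FPKM in hindgut and 7.60 in urethra. Of 6 secretory lineage genes, 4 were higher in hindgut and 1 in urethra (median -1.48, percentile 0). They included the secretory fate gene Atoh1 at 5.34 against 0.0048 FPKM, Dll4 at 2.73 against 0.093 and Gfi1 at 2.30 against 0.020, with Sct going the other way at 2.57 against 9.93; with a minimum of 5 FPKM the list's median turned to 0.79. It was -0.15 with no minimum and -0.47 with a pseudocount of 5. General endoderm and epithelium genes leaned to the hindgut, with 7 of 26 members higher there, none in urethra and a median of -0.59 at percentile 0. Foxa3 stood at 14.5 FPKM in hindgut against 0.40, the epithelial transcription factor genes Ehf at 81.9 against 7.35 and Elf3 at 25.4 against 7.22, and Cldn3 at 133 against 28.9. Foxa1 stood at 73.0 and 56.1 FPKM and Foxa2 at 47.5 and 30.3 in hindgut and urethra.

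Of 25 urethral and urothelial genes at E13.5, 8 were higher in urethra and 2 in hindgut, and 15 were within 2-fold, with a median of 0.43 at percentile 100 that was 0.16 with a minimum of 5 FPKM. Besides Krt14 and Gata3, Tbx3 stood at 75.1 FPKM in urethra against 6.59, Upk1b at 35.6 against 2.84 and Upk3a at 6.81 against 0.47. Upk1a stood at 30.0 FPKM in urethra and 49.9 in hindgut, and the 2 members higher in hindgut were Klf5 at 428 against 164 and Pparg at 3.60 against 0.087. Trp63 stood at 151 FPKM in urethra and 75.6 in hindgut, a ratio of 0.98 that lay past 2-fold after upper-quartile scaling or quantile normalization, at 1.01 and 1.11. The surface ectoderm and epidermis list had 9 of 15 members higher in urethra and none in hindgut (median 1.23, percentile 100), with Krt5 at 286 against 42.7 FPKM and Cldn1 at 6.06 against 0.11.

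Wnt genes again stood higher on the ventral side, with 9 of 27 members higher in urethra and 1 in hindgut (median 0.55, percentile 100). Wnt6 had 32.3 FPKM against 1.94, Lef1 10.3 against 0.58, the Wnt inhibitor gene Wif1 11.8 against 1.05, the receptor gene Fzd10 17.1 against 2.81 and Wnt5a 27.1 against 11.7. BMP and TGF-beta genes had 8 of 21 members higher in urethra and none in hindgut (median 0.66, percentile 100; 0.24 with no minimum), with Id3 at 214 FPKM against 39.0, Msx1 at 5.32 against 0.021, Inhba at 7.26 against 1.45 and Bmp4 at 30.3 against 19.9. For FGF, 2 of 20 were higher in urethra and 1 in hindgut (median 0.09, percentile 72.1): Fgfr2 at 78.1 against 31.8 FPKM, Fgf8 at 1.46 against 0.047 and Fgfr4 at 0.20 against 14.2. Among hedgehog genes 13 of 15 were within 2-fold (median 0.05, percentile 63.3). Ihh, the hedgehog ligand of the intestine, stood at 15.7 FPKM in hindgut against 0.74 and Gli2 at 2.84 against 0.78, while Shh had 118 FPKM in hindgut and 217 in urethra, a ratio of 0.88 that reached 1.03 under quantile normalization.

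The Notch list had 3 of 14 members higher in urethra and 1 in hindgut at E13.5 (median 0.10, percentile 77.6), with Nrarp at 17.9 against 4.13 FPKM, Hey1 at 13.2 against 4.78 and Jag2 at 22.6 against 9.64. Eph and ephrin genes had 4 of 18 higher in urethra and none in hindgut (median 0.47, percentile 100), with Efnb2 at 79.9 against 17.5 FPKM, Epha4 at 16.8 against 5.66, Epha7 at 19.0 against 8.16 and Epha5 at 1.55 against 0.12. Retinoic acid genes had 2 of 13 higher in urethra and none in hindgut (median 0.14, percentile 91.0), Crabp1 at 166 against 24.3 FPKM and Crabp2 at 15.6 against 2.91. Posterior Hox genes had 2 of 13 higher in each region (median 0.47, percentile 100; mean 0.04): Hoxd12 at 43.3 FPKM in urethra against 10.0, Hoxc10 at 1.92 against 0.30, and on the hindgut side Hoxb13 and Hoxb9, the latter at 2.46 against 6.04. Hoxd13 stood at 129 against 70.9 FPKM. Anterior and middle Hox genes had 2 of 15 higher in urethra and none in hindgut (median 0.05, percentile 41.6), Hoxd1 at 4.77 against 0.014 FPKM and Hoxd3 at 2.24 against 0.094.

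Genes of steroid hormone action were close to balanced at both ages, with 3 of 13 members higher ventrally and 1 dorsally at E10.5 (median 0.35, percentile 90.3), and 3 of 14 and 1 at E13.5 (median 0.18, percentile 91.8). Srd5a1 stood at 6.04 FPKM ventrally against 2.09 at E10.5, Esr1 at 1.72 against 0.29 at E13.5 (ratio 1.00 under quantile normalization, just short of 2-fold), and Tmprss2 at 7.97 against 18.7 and 8.65 against 19.3. Basement membrane and matrix genes leaned ventrally at both ages, with 7 of 25 members higher and 2 lower at E10.5 (median 0.48, percentile 99.9) and 5 of 26 and 2 at E13.5 (median 0.56, percentile 100). Col4a5 stood at 16.3 against 4.73 FPKM and Col4a6 at 9.18 against 2.37 at E10.5, and Col17a1 at 29.6 against 12.3 and Col4a2 at 29.7 against 12.5 at E13.5. Vtn at 0.71 against 18.8 FPKM at E10.5 and Fn1 at 84.7 against 232 at E13.5 went the other way. Cell cycle genes leaned slightly to the dorsal side at both ages, by less than 2-fold for most, with 28 of 30 members within 2-fold at E10.5 (median -0.20, percentile 1.67) and all 30 at E13.5 (median -0.24, percentile 0.25). The exceptions at E10.5 were Ccnb2 at 122 FPKM ventrally against 59.5, whose ratio was 0.99 under both other scalings, and Mcm4 at 24.2 against 49.4.

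**Figure D1:**
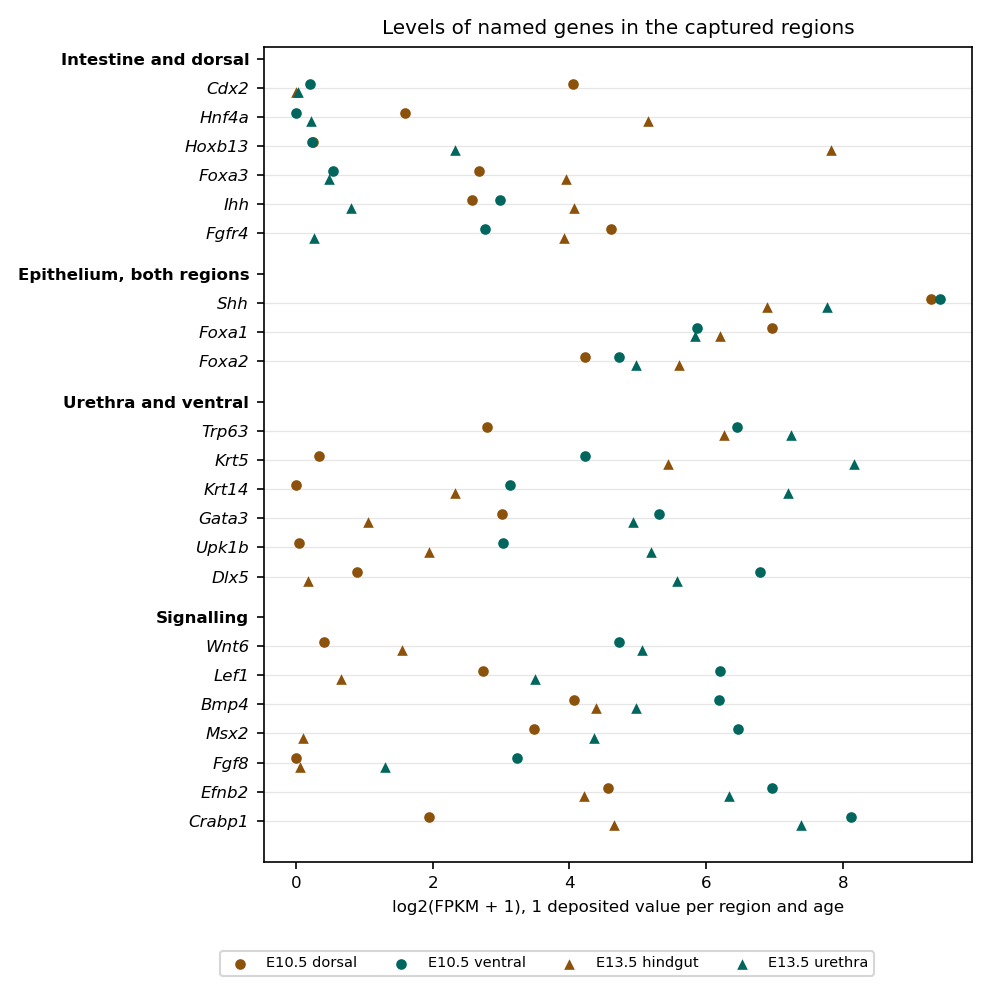
Levels of named genes as log2(FPKM + 1), circles for E10.5 and triangles for E13.5, brown for dorsal cloaca or hindgut and green for ventral cloaca or urethra, with 1 deposited value per point and no error. Krt14, Gata3, Upk1b, Dlx5, Wnt6 and Msx2 lie further right on the ventral side at both ages, and Hnf4a on the dorsal side.

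The third comparison asks how far the ventral-dorsal differences of the 2 ages agreed gene by gene. Some genes kept a 2-fold difference of the same direction, and most genes higher in a region at E10.5 did not. Named genes higher both in ventral cloaca and in urethra included Dlx5, Hdc, Gm16065, Crabp1, Wnt6, Lef1 and Msx2. Gata3, Krt5, Krt14, Upk1b, Tbx3, Efnb2 and Fgf8 were also among them. Clca3, Hnf4a, Foxa3, Cldn3 and Fgfr4 were among the named genes at least 2-fold higher on the dorsal side at both ages. Dusp5, a leading ventral gene at E10.5, stood at 0.75 FPKM in hindgut and 0.080 in urethra. Among 11486 genes above the minimum at both ages, 1075 were higher ventrally at E10.5 and 182 of these were higher in urethra, where independent lists would share 36.4. Of 943 higher dorsally, 136 were higher in hindgut, where they would share 32.9. Of these 2018 genes, 62.7% had a ratio of the same sign at E13.5. In opposite directions there were 52 genes higher ventrally and then in hindgut, against 37.5 for independent lists, and 43 higher dorsally and then in urethra, against 31.9. With a pseudocount of 5 these 4 counts of shared and opposite genes were 58, 32, 3 and 8, with one of 0.1 they were 286, 216, 99 and 100, and with a minimum of 5 FPKM they were 96, 71, 16 and 14. Across genes, which are not independent replicates, the ratios of the ages had a Pearson correlation of 0.26 and a Spearman correlation of 0.18. Among 2897 genes with a mean of at least 20 FPKM at both ages these correlations were 0.39 and 0.23. The ages share no embryos or libraries. The difference between ages was not tested for any gene.

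**Figure D2:**
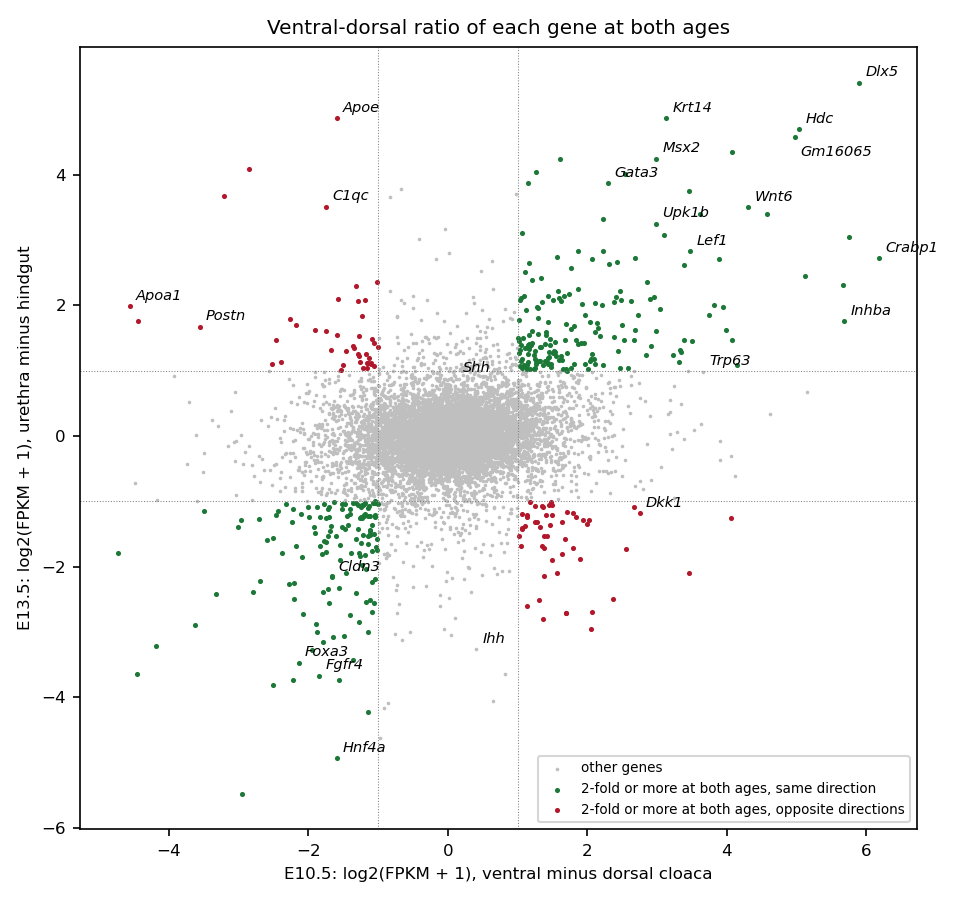
Each point is a gene with an FPKM of at least 1 in either region at both ages; the x axis is the log2(FPKM + 1) difference between ventral and dorsal cloaca at E10.5 and the y axis that between urethra and hindgut at E13.5, with dotted lines at 2-fold. The 182 and 136 genes of the same direction are green and the 52 and 43 of opposite directions red.

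Genes of other cell types that the captured pieces could hold differed between regions as well, beside the gene groups above. Macrophage genes stood higher in the E13.5 urethra, with 8 of 11 members higher, none lower and a median of 1.85 at percentile 100 that was 0.61 with a pseudocount of 5. Tyrobp stood at 20.3 FPKM against 0.55, the complement gene C1qc at 10.7 against 0.026 and Fcer1g at 9.44 against 0.12, and C1qb at 7.60 FPKM and listed at 0 in the hindgut. Of the 3 members within 2-fold, Laptm5 leaned to the hindgut, at 7.06 FPKM against 3.26 in urethra, a ratio of -0.92. At E10.5, 2 of 5 were higher dorsally (median -0.67, percentile 15.2), C1qc at 2.94 against 0.17 FPKM and Laptm5 at 1.25 against 0.077. Red blood cell genes leaned ventrally, with 2 of 8 members higher and 1 lower at E10.5 (median 0.73, percentile 99.3; 0.27 with no minimum) and 3 of 5 higher at E13.5 (median 1.05, percentile 99.97; 0.16 with no minimum). The embryonic globin gene Hbb-bh1 stood at 57.3 against 27.4 FPKM at E10.5, with Gata1 at 0.024 against 4.04. At E13.5 Hba-x had 16.4 FPKM in urethra against 5.13, Hbb-y 39.9 against 16.8 and the joint feature of Hbb-b1 and Hbb-b2 11.8 against 5.18. Of 14 endothelial genes only 4 passed the minimum at E10.5, and 3 of these were higher ventrally (median 1.76, percentile 99.9; 0.87 with a pseudocount of 5), Esam at 8.63 against 0.28 FPKM, Ramp2 at 13.7 against 2.14 and Erg at 1.46 and listed at 0 dorsally. Over all 14 members the median was 0.26. At E13.5 there were 1 of 4 higher and 1 lower (median 0.21, percentile 62.2), Erg at 3.15 against 0.071 FPKM and Sox18 at 0.11 against 1.82.

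Mesenchyme genes leaned dorsally at E10.5, with 6 of 19 members higher dorsally and 5 ventrally (median -0.43, percentile 1.09; -0.21 with no minimum). Postn, a matrix gene, stood at 28.7 FPKM dorsally against 1.52, while the limb field genes Tbx5 at 9.10 FPKM against 0.015 and Tbx4 at 5.02 FPKM and listed at 0 dorsally stood higher ventrally. At E13.5, 8 of 25 were higher in urethra and 4 in hindgut (median 0.15, percentile 81.9), with Prrx2 at 6.83 against 0.61 FPKM, Osr1 at 26.1 against 6.75 and Lum at 0.94 against 8.19. Smooth muscle genes had 1 of 5 members higher ventrally and 2 dorsally at E10.5 (median 0.19, percentile 60.9), Tagln at 2.2 against 0.35 FPKM, Des at 1.76 against 10.9 and Cnn1 at 1.80 dorsally and listed at 0 ventrally. At E13.5 there was 1 of 4 higher (median 0.76, percentile 97.4), Tagln at 2.44 against 0.45 FPKM. Neuron and neural crest genes had 2 of 7 higher dorsally at E10.5 (median 0.29, percentile 74.6), among them Ret at 7.03 against 2.2 FPKM. At E13.5 there were 2 of 6 higher in hindgut and 1 in urethra (median -0.45, percentile 3.75), Ednrb at 30.5 against 0.89 FPKM and Nefm at 1.44 against 0.22, with Hand2 at 0.18 against 2.36 in urethra; Nefm came within 2-fold under upper-quartile scaling.

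Germ cell genes had 1 of 6 members higher in each region at E10.5 (median -0.50, percentile 6.64), Tfap2c at 6.03 FPKM ventrally against 0.14 and Pou5f1 at 1.36 dorsally and listed at 0 ventrally, and 1 of 5 higher in hindgut at E13.5 (median -0.34, percentile 6.46), Kit at 28.6 against 7.11 FPKM. Nephric duct genes had 1 of 7 higher in each region at E10.5 (median -0.64, percentile 2.28; -0.13 with no minimum and -0.23 without shared loci) and 1 of 5 at E13.5 (median -0.60, percentile 0.49; -0.00024 with no minimum, -0.23 with a pseudocount of 5 and -0.14 with a minimum of 5 FPKM), with Gata3 higher ventrally at both ages and Ret dorsally at E10.5. Mesothelial genes had 3 of 8 higher ventrally and 1 dorsally at E10.5 (median 0.09, percentile 60.9), with Bnc1 at 2.2 against 0.012 FPKM and Lrrn4 at 3.16 against 0.68. At E13.5 there were 2 of 6 higher in urethra and 3 in hindgut (median -0.29, percentile 5.87), with Bnc1 at 3.93 against 0.12 FPKM, Msln at 0.46 against 3.79 and the epithelial keratin gene Krt19 at 293 against 846. Notochord and tail bud genes had 1 of 6 higher ventrally at E10.5 (median 0.57, percentile 95.5), which was Fgf8, and 1 of 6 higher in each region at E13.5 (median -0.15, percentile 23.7), Fgf8 in urethra and Foxj1 in hindgut at 6.70 against 0.83 FPKM. Stress genes had 3 of 16 higher ventrally and 5 dorsally at E10.5 (median -0.43, percentile 1.36), with Junb at 5.34 against 0.31 FPKM, Egr1 at 2.51 against 0.068, Jun at 13.4 against 44.4 and Ier3 at 2.30 against 7.75, and 1 of 19 higher in hindgut at E13.5 (median -0.27, percentile 1.09), Jun at 152 against 33.7 FPKM.

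**Figure D3:**
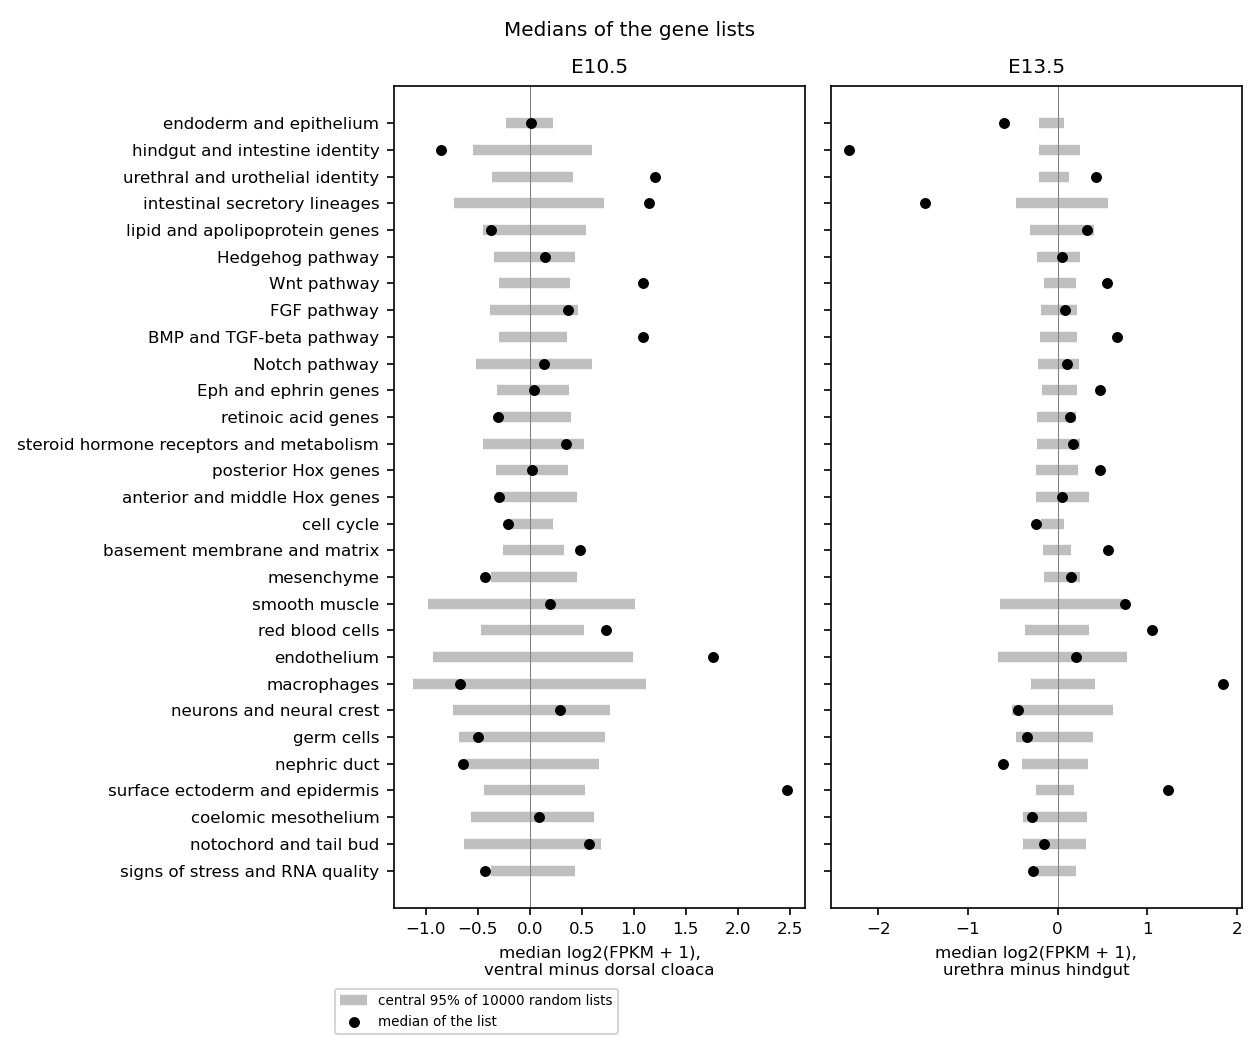
Black points are the medians of the log2(FPKM + 1) differences over each gene list at E10.5 (left) and E13.5 (right), and grey bars the central 95% of 10000 random lists of the same size and matched expression. The median of the hindgut and intestine list lies at -0.86 and -2.32, that of the surface ectoderm list at 2.47 and 1.23, and that of the macrophage list at -0.67 and 1.85.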

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

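Of the weighing below, the tests of non-epithelial tissue, of urethral cells in the hindgut and of keratin reads were chosen after the results were seen; the other tests were set before.

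Among the named genes and the short RNA features that the rule took, 7 were at least 2-fold higher on opposite sides at E10.5 and E13.5, and 1 of them, Klf5, was named after its values were seen. The difference between ages was not tested, since there is 1 value per region. Apoa1 had a log2 ratio of ventral to dorsal of -4.56 and then 1.99, a difference of 6.55. It was listed at 0 in the ventral cloaca, against 22.6 FPKM dorsally, so the first ratio depends on the pseudocount. The same holds for Mir3096, a microRNA feature that shares its locus, at 20.7 FPKM dorsally and listed at 0 ventrally, which had -4.44 and 1.76, a difference of 6.20. Apoe had -1.59 and 4.87, a difference of 6.46. C1qc had -1.75 and 3.51, a difference of 5.26. Postn had -3.56 and 1.67, a difference of 5.23. Dkk1 had 2.75 and -1.18, a difference of -3.93. Klf5 had 1.11 and -1.38, a difference of -2.49.

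More genes were 2-fold apart at E10.5 than at E13.5, 2499 against 1083. Scaling between the regions is argued against, because after quantile normalization the count at E10.5 was still 2.30 times that at E13.5 (2486 against 1080). Weakly expressed genes are argued against as the whole cause, because among genes with a mean of at least 20 FPKM the count was 1.64 times as large (288 against 176). A wider measurement spread at E10.5 stays open as a candidate explanation: over 115 proteasome, complex I and translation initiation genes the SD of the ratio was 0.41 at E10.5 and 0.23 at E13.5, 1.76 times as wide, although over 73 ribosomal protein genes it was narrower at E10.5, 0.15 against 0.21. A difference of age between the embryos stays open, untested.

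Macrophage genes, among them C1qc, stood higher in the E13.5 urethra. A rise of mesenchyme to the same extent is argued against. Over 33 genes of mesenchyme, smooth muscle and endothelium, 25 of them mesenchymal, the median ratio was 0.30 (SD 1.1). This is below the 1.85 of the macrophage list by 1.55. With red blood cell and neuron genes added the median over 44 genes was 0.33 (SD 1.22), below it by 1.52. With a pseudocount of 5 the medians were 0.61 for macrophage, 0.06 for mesenchyme and 0.72 for red blood cell genes. Smooth muscle genes at 0.76 and red blood cell genes at 1.05 leaned to the urethra as well, so more blood or muscle there stays open. Endoderm and epithelium genes leaned to the hindgut, at -0.59, so more non-epithelial tissue in the captured urethra also stays open. More macrophages in the captured urethra stay open as a candidate source that was not settled: over a second list the 12 genes above the minimum had a median of 1.26, with 8 higher and 1 lower, but 7 of these 8 reached the minimum in urethra only, and over all 30 genes, most of them near 0, the median was 0.45, with 25 leaning to the urethra and 5 to the hindgut. Its most abundant genes were Cyba at 46.2 FPKM in hindgut and 22.8 in urethra, Arhgdib at 3.20 and 23.3, Lcp1 at 12.5 and 11.6 and Ctsc at 6.31 and 4.58, and these 4 were above 1 FPKM in all 4 regions; which cells carried them, and whether tissue or capture held more macrophages, was not tested.

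Several genes of stratified and urothelial epithelium were at similar levels in hindgut and urethra at E13.5, or higher in hindgut, Krt15 at 517 and 474 FPKM, Sfn at 218 and 139, Klf5 at 428 and 164, and Upk2 at 50.5 and 43.0. Urethral cells captured with the hindgut are argued against as the whole cause. Among the top ventral genes of E10.5, 8 had at least 5 FPKM in urethra. Over these 8 the level in hindgut had a median of 8.94% of that in urethra. The minimum in urethra favours low percentages. It left out Dlx6, at 4.46 FPKM in urethra and listed at 0 in hindgut. Dusp5 was also left out, at 0.080 FPKM in urethra and 0.75 in hindgut. Urethral cells in the hindgut could also not bring Klf5 to 261% or Sfn to 157%. The 8 genes ranged from 0.27% for Dlx5 to 58.0% for Adamtsl5, so a smaller share of such cells stays open. Whether all urethral cells carry these 8 genes was not tested. Reads shared between keratin genes are argued against as the whole cause, because 14 members that are not keratins had a median of 90.2%, with 10 at 50% or more. Sfn, Klf5 and Upk2, which stated the pattern, are among these 14. For the keratins themselves, such as Krt15, shared reads stay open, because they were left out here. Other stratified epithelium near the hindgut, and a difference between the regions themselves, stay open, untested.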

How the results depend on the processing

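The alternatives without short RNA features, without shared loci and without zeros were chosen after seeing the data. No paired analysis was possible because the tables hold 1 value per region, and for the same reason the fits without the embryo block, with array weights or without the trend, leaving out each embryo, camera with an estimated correlation, fry and an adjusted p of 0.1 were not run. The pseudocount decided the counts most. With a pseudocount of 5 there were 401 genes higher in ventral and 325 in dorsal cloaca, 173 in urethra and 227 in hindgut; at both ages 58 were higher ventrally and 32 dorsally, and 3 and 8 lay on opposite sides. With 0.1 there were 864 higher in urethra; at both ages 286 were higher ventrally and 216 dorsally, and 99 and 100 lay on opposite sides. A larger pseudocount shrinks the ratios of low genes by construction. With a minimum of 5 FPKM, which leaves fewer genes, there were 823 and 691 at E10.5, and 298 in urethra and 387 in hindgut. At both ages there were 96 and 71, with 16 and 14 on opposite sides. Among lists whose median lay outside the central 95% of random lists, only that of the intestinal secretory genes at E13.5 changed sign, from -1.48 to 0.79 under that minimum. Medians inside it changed sign more often, such as smooth muscle at E10.5, from 0.19 to -0.96 without shared loci. With no minimum the counts of genes were the same, since a gene below 1 FPKM cannot pass 2-fold with a pseudocount of 1. List medians did change: of 58 medians, 11 that lay outside the central 95% came to less than 50% of their size with no minimum, 9 with a pseudocount of 5, 3 with a minimum of 5 FPKM and 1 without shared loci. Both other scalings and the 3 alternatives added later kept each count within 1.5 times, and each scaling moved 4 of 269 named ratios, 24 of them of short RNA features, across 2-fold. With a pseudocount of 5, 88 of 269 crossed it, and with one of 0.1 it was 1. No named gene that was 2-fold apart changed direction under any alternative in which it was kept. The Pearson correlation of the ages lay between 0.21 and 0.32 under these alternatives. Unknown depth and the lack of values per embryo limit every ratio, most of all those of genes near 0.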

Other observations

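The test of the Hox genes was chosen after their values were seen.

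Embryonic globin RNA was abundant in both parts of the cloaca. At E10.5 Hba-x stood at 585 FPKM dorsally and 708 ventrally and Hbb-y at 239.9 and 350.3. At E13.5 Hba-x stood at 5.13 and 16.4 FPKM in hindgut and urethra. Such levels are set side by side across tables that were normalized separately.

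Further members of the hindgut and intestine list differed between hindgut and urethra at E13.5, and others were near 0 in both. Tff3, a peptide gene of goblet cells, stood at 19.2 FPKM against 1.59 in urethra, Tspan8 at 53.8 against 8.08, Isx at 5.10 against 0.057 and Cdh17 at 3.62 against 0.051. Slc26a3 and Car1 were listed at 0 in both, Muc13 stood at 0.29 and 0.46 FPKM and Cdhr5 at 0.0060 and 0.020. Fabp1, a fatty acid binding protein gene of gut and liver, was at 158 FPKM in dorsal and 36.4 in ventral cloaca, and at 0.45 in hindgut and listed at 0 in urethra. The list of lipid and apolipoprotein genes had 1 of 11 members higher ventrally and 3 dorsally at E10.5 (median -0.38, percentile 4.79), and 4 of 12 higher in urethra and 1 in hindgut at E13.5 (median 0.32, percentile 93.4). Dab2 stood at 32.7 against 11.5 FPKM and at 17.0 against 3.08, Afp at 5.52 against 12.5 at E10.5, Ttr at 4.38 against 1.16 at E13.5, and Alb at 2.94 FPKM in hindgut and listed at 0 in urethra.

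Hoxb13 stood at 0.19 and 0.18 FPKM in dorsal and ventral cloaca and at 227 and 4.04 in hindgut and urethra, whereas Hoxa13 stood at 53.3 and 188 FPKM and then at 73.8 and 141. Cdx2 stood at 15.5 FPKM in the dorsal cloaca and was listed at 0 in the hindgut, where Cdx1 stood at 18.3 FPKM. These levels too come from tables normalized separately. A listed 0 can be a failed estimate, so a loss of Cdx2 RNA from the hindgut is not shown.

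The high ventral ratios of Hoxd12, Hoxd13 and Hoxa13 raise the hypothesis that the ventral-dorsal ratio follows a gene's place in the Hox cluster. Across 20 HoxA and HoxD genes, which are not independent replicates, Spearman's rho between paralog number and ratio was 0.23 at E10.5 (two-sided permutation p = 0.33) and 0.32 at E13.5 (p = 0.16). Pearson's r was 0.27 (p = 0.25) and 0.09 (p = 0.71). The clusters gave different values, a difference that was not tested: within 11 HoxA genes rho was 0.35 and 0.42 and r 0.44 and 0.51 at the 2 ages, and within 9 HoxD genes rho was 0.15 and -0.05 and r 0.09 and -0.38, with no test within a cluster. Over the 4 pooled relations the adjusted p was 0.44, 0.44, 0.44 and 0.71. The relation was not established, and 20 genes are too few to exclude a modest one. HoxB and HoxC genes were left out, among them Hoxb13 with a ratio of -5.50 at E13.5 and Hoxc11 with 2.37 at E10.5.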
